A study of Mus musculus with 6 samples.

How the data were processed

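Total RNA of mouse liver was extracted with Trizol and sequenced on an Illumina instrument, per the labels, in 2 libraries each of the title prefixes C, S and X. The values were estimated counts per gene, whole numbers in a single table made by the submitters as deposited. Per the submitters' processing notes reads were aligned with HISAT2 (version not given) to GRCm39. The counter, its settings, the annotation and the strand setting were not given in the sources used here. A value of 4 was more frequent than a value of 1, in 467 to 803 genes per library against 196 to 322, for a reason not given in the sources used here, so 1 unit may not be 1 sequenced fragment and counting error was not read from the values. The table had 46333 entries and 46329 distinct symbols. The 3 symbols on 7 entries were kept as separate entries, with the plain symbol on the first of each. The design had named the entry with the highest total instead, and this was not carried out. Gene symbols were used as given, and transcript length and GC content came from a GENCODE reference of GRCm38, matched by symbol for 84.5% of the genes tested, with no coordinates used.

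Groups were taken from the title prefixes, and the samples, comparisons, tests, gene lists and alternatives were fixed before the data were examined. Library totals ranged from 86156027 to 232888506 estimated counts. Replicates correlated at r = 0.967 in C, 0.969 in S and 0.974 in X on log2 CPM. The biological coefficient of variation was 28.5%.

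Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and 1 quasi-likelihood model with a mean per group was fitted to all 6 libraries, leaving 3 residual degrees of freedom. Each of C minus S, X minus S and X minus C was tested on both sides with Benjamini-Hochberg adjustment over 21289 genes at a false discovery rate of 0.05. The design had named the defaults of edgeR version 4 for this fit and its legacy form as an alternative. The installed version uses the legacy form by default, so the default was kept and the newer form became the alternative. Levels are CPM, counts divided by the TMM-scaled library total and multiplied by a constant, given as mean ± SD, and log2 differences are model estimates ± SE. PCA and distances used log2 CPM with a prior count of 2, distances over the 500 genes of largest variance.

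The design fixed 52 lists with 837 members, of which 826 were in the table and 800 were tested. Lists with at least 3 tested members, 51 in number, were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over lists within a comparison. Members that passed were counted with adjustment over all genes and over the list alone. At the preset value 25 passed in C minus S, 24 in X minus S and 24 in X minus C. With the correlation estimated from the data, camera passed 0 lists in each comparison, with 5, 2 and 2 at an unadjusted p under 0.05, and fry passed 29, 18 and 16. The correlation of log2 differences between comparisons that share a group was set beside 100 simulated draws with no group effect. Overlaps of calls were set beside 20 such draws, refitted, with lists taken by p at the observed sizes, a test added after the overlaps were seen.

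Genes named in the text follow a rule fixed in the design. Per comparison these were, first, the 10 largest positive and 10 largest negative log2 differences among genes that passed with a mean of at least 8 CPM, both libraries of one group above both of the other, and a symbol that is not a predicted or clone name. Added to these were up to 4 members of each list with the smallest adjusted p among those that passed, and in every comparison Saa1, Lcn2, Alb, Cyp7a1, Cyp2e1, Lgals1, Lgals3, Lgals9, Havcr2 and Cd8a. The examples given were picked from this set after their values were seen, and some genes of the set are not reported here.

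The procedure was tested on simulated data with 200 changed genes, 50 at each fold. For C minus S, X minus S and X minus C it recovered 34%, 26% and 48% of 2-fold changes, 62%, 70% and 62% of 4-fold changes, and 80%, 72% and 84% of 8-fold changes, with 2, 7 and 6 false calls. At 1.5-fold it recovered 6%, 10% and 0%. Far fewer genes were changed in this simulation than passed in the data, and the Benjamini-Hochberg cut depends on that number. These rates are therefore not the sensitivity in the data.

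The alternatives fixed in advance were other scalings (RLE, upper quartile, totals alone), no filter or a stricter filter, DESeq2 1.42.0, limma-voom, the newer quasi-likelihood form, a robust prior, a fit of the 4 libraries compared, the 20 most abundant genes or all mitochondrial genes left out, a test against 1.5-fold, and each library left out. For lists they were an estimated correlation, fry, ranks, another prior count, no filter, RLE and each library left out. A fit without a library left a single library in its group and fewer residual degrees of freedom, so calls could end through lost power alone. After the data were seen 4 were added: counts divided by 4, thinning to the shallowest library, a loess correction for GC content and length, and leaving out short, transfer RNA, ribosomal RNA and mitochondrial genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.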

Results

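Mouse liver was profiled by RNA sequencing of total RNA in 6 samples, with tissue taken after 24 h. The design divided mice into CLP, control and alpha-lactose arms. CLP is in mouse work the usual short form of cecal ligation and puncture, a surgical model of abdominal sepsis, although the labels did not spell it out. Alpha-lactose is a sugar that binds galectins, a family of proteins that recognise glycans. The sample titles carry the prefixes C, S and X with 2 libraries each, and neither the titles nor the design text say which prefix is which arm. The groups are therefore called C (replicates 19 and 21), S (replicates 5 and 7) and X (replicates 1 and 3), and each pair was compared. The labels did not say whether the alpha-lactose mice also underwent CLP. The labels also did not say whether the samples came from separate animals, so p-values measure the spread between these samples. Library totals were 130430768 and 130595110 estimated counts in C, 98179087 and 86156027 in S, and 208209707 and 232888506 in X, and 21289 genes entered the tests.

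The libraries separated by group. The root mean square log2 difference over the 500 most variable genes was 2.14 between the C replicates, 2.01 between the S replicates and 1.8 between the X replicates. Between groups it ranged from 5.06 to 5.56 for C and S, from 3.37 to 3.89 for C and X, and from 3.39 to 3.8 for S and X. These genes were picked by variance over the same libraries, which favours genes that differ between groups. Distances within groups were not computed over all tested genes. The 20 most abundant genes took 36.9% and 36.8% of the counts in C, 23.8% and 25% in S, and 36.6% and 37.1% in X. Alb, which encodes serum albumin, did not pass the test in any comparison, with 29600 ± 7190 CPM (SD, n = 2) in C, 42660 ± 13430 CPM in S and 32390 ± 3569 CPM in X.

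**Figure D1:**
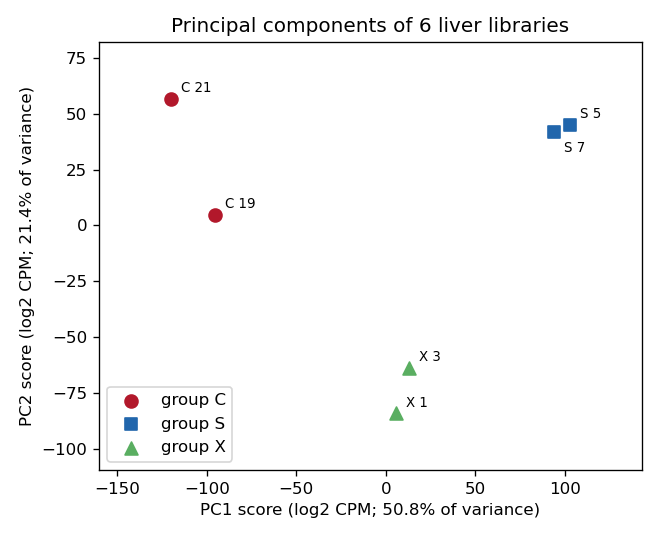
Scores of the 6 libraries on the first and second principal components of log2 CPM over the tested genes, with group shown by colour and marker shape. The first axis carried 50.8% of the variance and placed C replicates 19 and 21 at -95.3 and -120, S replicates 5 and 7 at 103 and 94.1, and X replicates 1 and 3 at 5.85 and 12.9. The second axis carried 21.4% and, in the same order, placed C at 4.61 and 56.5, S at 44.9 and 41.8, and X at -84 and -63.7.

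The comparison of C with S asked how the livers of these arms differed at 24 h. Acute phase and innate immune genes were far higher in C. Saa3, an inducible serum amyloid A gene, stood at 2198 ± 44.7 CPM (SD, n = 2) in C and 4.35 ± 3.02 CPM in S, a log2 difference of 8.99 ± 0.58 (SE). Cd14, a co-receptor for bacterial lipopolysaccharide, stood at 556 ± 176 CPM against 1.57 ± 0.191 CPM and was 354-fold higher. Il1rn, which encodes the antagonist of the interleukin-1 receptor, was 147-fold higher, and Lcn2, a lipocalin that binds iron-carrying siderophores, was 15.3-fold higher. Saa1 was 4.02-fold higher (adjusted p = 0.0188), with the S replicates apart at 919 and 2893 CPM. Reg3g, an antibacterial lectin, reached 118 ± 20.3 CPM in C and 0.0427 ± 0.0604 CPM in S. Of 28 acute phase genes, 20 rose in C, 0 fell and 8 did not pass, and 24 rose when adjusted over the list alone. Their median log2 difference was 1.81 (camera adjusted p = 3.56e-09, and adjusted p = 0.392 with an estimated correlation). Saa1 may share reads with its near copy Saa2.

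Inflammatory signalling moved in the same direction. Of 20 genes of NF-kappaB and Toll-like receptor signalling, 15 rose, 1 fell and 4 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 4.58e-06, and adjusted p = 0.344 with an estimated correlation). Tnfaip3 and Irak3, brakes on this pathway, were 22.3-fold and 26.4-fold higher, and Socs3, a feedback inhibitor of cytokine receptors, was 5.62-fold higher. Of 22 cytokines and chemokines, 12 rose, 1 fell and 9 did not pass, and 13 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.000613, and adjusted p = 0.344 with an estimated correlation). Cxcl1, a neutrophil attractant, stood at 286 ± 30.3 CPM in C and 16.3 ± 11.5 CPM in S, and Il33, an alarm cytokine, was 13.2-fold higher. Among 27 interferon-stimulated genes 17 rose, 0 fell and 10 did not pass, and 20 rose adjusted over the list alone (camera adjusted p = 1.23e-05, and adjusted p = 0.344 with an estimated correlation). Rsad2 and Ifit1, both antiviral effectors, were 4.06-fold and 3.52-fold higher. Without S replicate 5 or without S replicate 7 the counts that rose were 7 in each case for the cytokines and 11 in each case for the interferon list.

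Unfolded protein response, ribosomal and immediate early genes were also higher in C, while heat shock and antioxidant genes were not as a group. Of 19 unfolded protein response genes, 12 rose, 0 fell and 7 did not pass, and 17 rose adjusted over the list alone (camera adjusted p = 4.58e-06, and adjusted p = 0.344 with an estimated correlation). Creld2 and Manf, secreted products of endoplasmic reticulum stress, were 3.66-fold and 2.42-fold higher, and the chaperone Hspa5 rose from 954 ± 3.11 CPM in S to 2115 ± 13.6 CPM in C. Of 30 cytosolic ribosomal protein genes, 27 rose, 0 fell and 3 did not pass, and 29 rose adjusted over the list alone. Their median log2 difference was 0.66 (camera adjusted p = 6.68e-09, and adjusted p = 0.344 with an estimated correlation), with Rps15a 1.89-fold and Rps27a 2.53-fold higher. Of 15 immediate early genes, 7 rose, 0 fell and 8 did not pass, and 11 rose adjusted over the list alone (camera adjusted p = 4.27e-05, and adjusted p = 0.344 with an estimated correlation). Ier3, a stress-induced survival gene, stood at 42.1 ± 21.2 CPM in C and 0.417 ± 0.122 CPM in S. Of 18 p53 target and apoptosis genes, 10 rose, 1 fell and 7 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.000613, and adjusted p = 0.344 with an estimated correlation), led by the cell cycle inhibitor Cdkn1a at 33.1-fold. Of 10 metallothionein and metal handling genes, 7 rose, 1 fell and 2 did not pass, and 8 rose adjusted over the list alone (camera adjusted p = 0.00855, and adjusted p = 0.344 with an estimated correlation), among them Mt1 at 6.06-fold. Without S replicate 5 the counts that rose were 9 ribosomal, 7 unfolded protein response and 5 metal handling genes, and without S replicate 7 they were 16, 10 and 4. Of 10 heat shock genes, 2 rose, 6 fell and 2 did not pass, and 2 rose and 7 fell adjusted over the list alone (camera adjusted p = 0.0629, 0.0352 with no filter, 0.0159 by fry, 0.0308 without C replicate 21 and 0.0471 without S replicate 7). Hsph1, a chaperone of the HSP110 family, was 3.24-fold lower. This list had 1 that rose and 3 that fell without S replicate 5, 0 and 4 without S replicate 7, and 1 and 4 without C replicate 21. Of 16 oxidative stress and NRF2 target genes, 8 rose, 5 fell and 3 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.325). Sod2, the mitochondrial superoxide dismutase, was 5.5-fold higher and Cat, catalase, 8.3-fold lower. The list had 5 that rose and 4 that fell without S replicate 5, and 5 and 3 without S replicate 7.

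Genes of drug, bile acid and amino acid metabolism were lower in C. Of 31 genes of cytochrome P450 and drug metabolism, 24 fell, 0 rose and 7 did not pass, and 28 fell adjusted over the list alone. Their median log2 difference was -1.91 (camera adjusted p = 3.56e-09, and adjusted p = 0.344 with an estimated correlation). Cyp2e1, which oxidises ethanol and paracetamol, stood at 1274 ± 428 CPM in C and 5596 ± 651 CPM in S, and Gsta3 and Cyp3a25 were each 15-fold lower. Nr1i3, the nuclear receptor CAR, was 5.8-fold lower. Of 20 bile acid genes, 16 fell, 1 rose and 3 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 4.58e-06, and adjusted p = 0.344 with an estimated correlation). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 167 ± 120 CPM in S and 0.0775 ± 0.11 CPM in C, where replicate 21 had a count of 0. Cyp8b1 was 22.9-fold lower, the bile salt export pump Abcb11 23-fold lower, and the bile acid uptake carrier Slc10a1 10.3-fold lower. Of 26 urea cycle and amino acid catabolism genes, 15 fell, 4 rose and 7 did not pass, and 16 fell and 5 rose adjusted over the list alone (camera adjusted p = 0.000613, and adjusted p = 0.454 with an estimated correlation). Without S replicate 7 the genes of this list that rose were 2. Cth, which makes cysteine, was 21.5-fold lower.

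Lipid and glucose genes went both ways in C against S. Of 28 fatty acid oxidation genes, 6 rose, 8 fell and 14 did not pass, and 6 and 9 did so adjusted over the list alone (camera adjusted p = 0.398). Pdk4, which spares glucose by blocking pyruvate dehydrogenase, was 13.2-fold higher and the ketone body enzyme Bdh1 3.63-fold lower. Of 25 lipogenesis and triglyceride genes, 5 rose, 7 fell and 13 did not pass, and 5 and 8 did so adjusted over the list alone (camera adjusted p = 0.732). The lipid droplet gene Plin2 was 5.83-fold higher and Mlxipl, which encodes the carbohydrate sensor ChREBP, 3.32-fold lower. Of 17 gluconeogenesis and glucose genes, 4 rose, 6 fell and 7 did not pass, and 6 and 7 did so adjusted over the list alone (camera adjusted p = 0.652). The glucose transporter Slc2a2 was 18-fold lower, while the glycolytic regulator Pfkfb3 was 6.55-fold and the gluconeogenic enzyme Fbp1 2.5-fold higher. Of 22 cholesterol genes, 3 rose, 3 fell and 16 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.767). In the order fatty acid, lipogenesis, glucose and cholesterol, the genes that rose and fell were 4 and 4, 5 and 4, 3 and 5, and 1 and 3 without S replicate 5. They were 5 and 5, 4 and 8, 2 and 4, and 3 and 3 without S replicate 7, and 3 and 12, 4 and 5, 3 and 8, and 3 and 5 without C replicate 21.

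Zonation and secretion genes fell in C as well. Of 15 pericentral and WNT target genes, which mark hepatocytes near the central vein, 14 fell, 0 rose and 1 did not pass, and 15 fell adjusted over the list alone (camera adjusted p = 6.65e-07, and adjusted p = 0.344 with an estimated correlation). Of 13 periportal genes, 8 fell, 1 rose and 4 did not pass, and 10 fell adjusted over the list alone (camera adjusted p = 0.000613, and adjusted p = 0.344 with an estimated correlation). The glutamate transporter Slc1a2 and the WNT feedback gene Axin2, on the pericentral side, were 5.97-fold and 3.37-fold lower, and Cyp2f2 and the histidine-degrading enzyme Hal, on the periportal side, were 6.06-fold and 5.22-fold lower. Of 31 complement and coagulation genes, 19 fell, 3 rose and 9 did not pass, and 20 fell and 4 rose adjusted over the list alone (camera adjusted p = 0.000484, and adjusted p = 0.344 with an estimated correlation). Klkb1, plasma prekallikrein, was 28.3-fold lower. Against the direction of most of the list, Thbd, which encodes the anticoagulant thrombomodulin, rose with a log2 difference of 4.18 ± 0.21 (SE). Of 18 hepatocyte transcription factors, 10 fell, 0 rose and 8 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.00165, and adjusted p = 0.344 with an estimated correlation), among them Cebpa at 2.53-fold lower.

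Neutrophil markers rose in C against S, while other non-parenchymal markers fell or went both ways. Of 16 neutrophil markers, 13 rose, 0 fell and 3 did not pass, and 15 rose adjusted over the list alone. Their median log2 difference was 4.14 (camera adjusted p = 4.84e-08, and adjusted p = 0.344 with an estimated correlation). Ltf, lactoferrin of neutrophil granules, stood at 11.3 ± 1.03 CPM in C and 0.0214 ± 0.0302 CPM in S, and Mmp8 and Mmp9 were 28.2-fold and 15.8-fold higher. Of 14 liver sinusoidal endothelial markers, 9 fell, 3 rose and 2 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.0145, and adjusted p = 0.415 with an estimated correlation). Clec4g, a lectin of these cells, was 50.2-fold lower and Dnase1l3 was 14.9-fold lower, whereas Lyve1, also a lymphatic marker, was 10.3-fold higher. Of 12 Kupffer cell markers, which mark the resident liver macrophages, 7 fell, 3 rose and 2 did not pass, and 8 fell and 3 rose adjusted over the list alone (camera adjusted p = 0.0813, 0.0376 without C replicate 21 and 0.00894 by fry). Vsig4 and Clec4f were 4.22-fold and 4.59-fold lower, while the scavenger receptor Marco was 14.5-fold higher. Of 9 B and plasma cell markers, 4 fell and 5 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.00165, and adjusted p = 0.344 with an estimated correlation). Without S replicate 7 the Kupffer list had 4 genes that fell, without S replicate 5 it had 5 that fell and 1 that rose, and without C replicate 21, S replicate 5 or S replicate 7 the B cell list had 1.

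Blood and myeloid markers moved too. Of 8 erythroid and blood markers, 6 fell, 0 rose and 2 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.00591, and adjusted p = 0.454 with an estimated correlation and adjusted p = 0.0583 by fry). Alas2, which starts heme synthesis in red cells, was 1.87-fold lower. Of 17 monocyte and macrophage markers, 6 rose, 3 fell and 8 did not pass, and 7 and 3 did so adjusted over the list alone (camera adjusted p = 0.205, and adjusted p = 0.0227 by fry). Chil3, a chitinase-like protein of myeloid cells, was 66.7-fold higher and the integrin gene Itgam 13.6-fold higher. Of 9 dendritic cell markers, 2 fell, 0 rose and 7 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.00628, and adjusted p = 0.385 with an estimated correlation), with Siglech, a lectin of plasmacytoid cells, 8.62-fold lower. The erythroid genes that fell were 2 without C replicate 19, 1 without S replicate 5 and 4 without S replicate 7. The monocyte list had 4 that rose and 1 that fell without S replicate 5 or without S replicate 7, and the dendritic list had 1 that fell without C replicate 21, S replicate 5, S replicate 7, X replicate 1 or X replicate 3.

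In total 6073 of 21289 genes differed between C and S by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at a false discovery rate of 0.05. Of these 3003 were higher and 3070 lower in C, so that 49.4% were higher. Scaling by library totals alone gave 6018 genes with 32.4% higher and put the median of all genes at -0.22 on the log2 scale, from -0.0059. The count was 3374 without S replicate 5, 3619 without S replicate 7 and 2753 when a change beyond 1.5-fold was required.

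**Figure D2:**
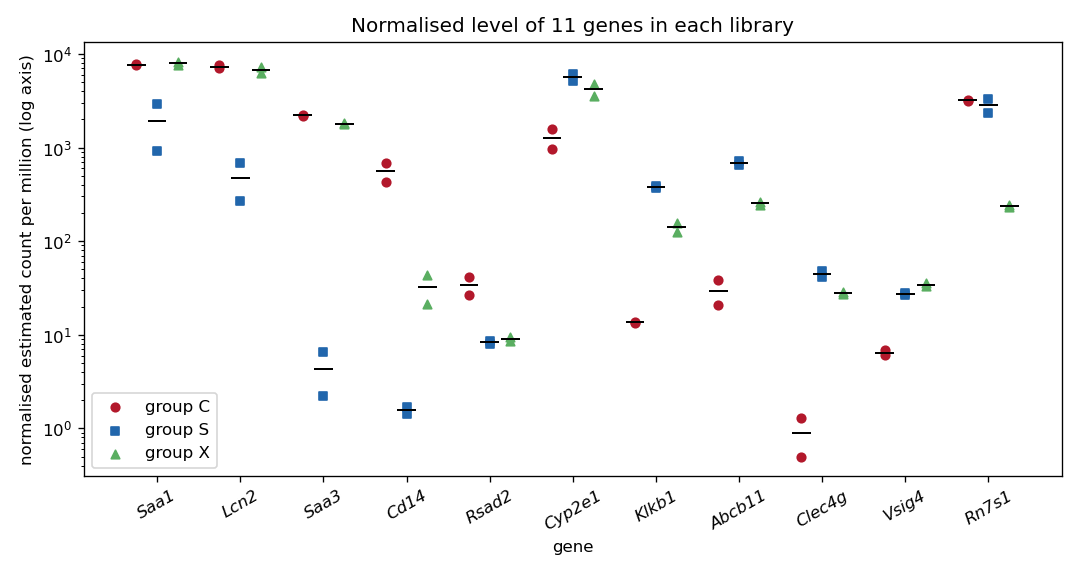
CPM of 11 genes on a log axis, with 1 point per library and a bar at each group mean of 2 libraries. Cd14 was highest in C and lowest in S with X between, Saa1 and Lcn2 in X lay near C, Rsad2 in X lay near S, and Rn7s1 was lowest in X.

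The comparison of X with S again showed a higher acute phase. Saa3 reached 1796 ± 40.6 CPM (SD, n = 2) in X and was 414-fold above S, and Lcn2 reached 6747 ± 599 CPM, 14.1-fold above S. Il1rn was 31.3-fold higher and Cd14 20.7-fold higher. Saa1 was 4.16-fold higher (adjusted p = 0.0319), a call that ended without X replicate 1 (adjusted p = 0.143) and without X replicate 3 (adjusted p = 0.119). Of 28 acute phase genes, 22 rose in X, 0 fell and 6 did not pass, and 27 rose adjusted over the list alone. Their median log2 difference was 1.63 (camera adjusted p = 1.72e-14, and adjusted p = 0.411 with an estimated correlation). Of 16 neutrophil markers, 11 rose, 0 fell and 5 did not pass, and 13 rose adjusted over the list alone (camera adjusted p = 2.48e-08, and adjusted p = 0.411 with an estimated correlation), with Mmp8 17.3-fold and S100a8, a subunit of calprotectin, 8.63-fold higher. Of 20 NF-kappaB and Toll-like receptor genes, 9 rose, 1 fell and 10 did not pass, and 15 rose adjusted over the list alone (camera adjusted p = 3.18e-06, and adjusted p = 0.411 with an estimated correlation), with Tnfaip3 8-fold higher. Of 19 unfolded protein response genes, 10 rose, 0 fell and 9 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.000773, and adjusted p = 0.411 with an estimated correlation), with Creld2 3.57-fold and Manf 2.62-fold higher. Without X replicate 1 the counts that rose were 8, 9, 5 and 2 in these 4 lists, and without X replicate 3 they were 10, 8, 5 and 7. Without S replicate 5 they were 17, 9, 6 and 5, and without S replicate 7 they were 25, 9, 8 and 5.

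Interferon-stimulated genes did not move as a group in X against S. Of 27 genes, 2 rose, 2 fell and 23 did not pass, and 3 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.35). Rsad2 stood at 9.09 ± 0.68 CPM in X and 8.36 ± 0.448 CPM in S, with a log2 difference of 0.12 ± 0.21 (SE). Of 15 immediate early genes, 3 rose, 2 fell and 10 did not pass, and 4 and 2 adjusted over the list alone (camera adjusted p = 0.481), while 4 rose and 0 fell after the GC and length correction or without S replicate 7, and none passed without S replicate 5 or X replicate 3. Without X replicate 1 no gene of either list passed, and without C replicate 19 the interferon list had 5 that rose and 5 that fell.

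Hepatocyte metabolism was partly lower in X than in S. Of 31 cytochrome P450 and drug metabolism genes, 17 fell, 0 rose and 14 did not pass, and 21 fell adjusted over the list alone (camera adjusted p = 3.42e-08, and adjusted p = 0.411 with an estimated correlation). Cyp2f2 was 5.96-fold lower and Gsta3 5.01-fold lower, while Cyp2e1 stood at 4195 ± 876 CPM in X with a log2 difference of -0.42 ± 0.27 (SE, adjusted p = 0.359). Of 20 bile acid genes, 10 fell, 1 rose and 9 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.00174, and adjusted p = 0.411 with an estimated correlation). The organic anion carrier Slco1a1 was 5.65-fold lower, and Cyp7a1 was 86-fold lower (adjusted p = 0.00512), a call that ended without X replicate 1 (adjusted p = 0.0709). Hsd3b5, a steroid reductase typical of male mouse liver whose near copies may share its reads, stood at 1.27 ± 0.0137 CPM in X and 117 ± 19.8 CPM in S. Of 22 cholesterol synthesis and uptake genes, 11 fell, 0 rose and 11 did not pass, and 12 fell adjusted over the list alone (camera adjusted p = 0.000234, and adjusted p = 0.411 with an estimated correlation). Without X replicate 1 the counts that fell were 2 for drug metabolism, 2 for bile acids and 0 for cholesterol, and without X replicate 3 they were 7, 5 and 1. Without S replicate 5 they were 10, 5 and 4, and without S replicate 7 they were 16, 5 and 4.

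Mitochondrial and small RNA genes set X apart from S. Of 13 mitochondrially encoded genes, 7 rose, 0 fell and 6 did not pass, and 10 rose and 1 fell adjusted over the list alone (camera adjusted p = 8.14e-05, and adjusted p = 0.411 with an estimated correlation). ND6, a subunit of respiratory complex I, was 2.71-fold higher. After the GC and length correction 2 of these genes rose and 1 fell. Of 29 nuclear-encoded oxidative phosphorylation genes, 12 fell, 0 rose and 17 did not pass, and 17 fell adjusted over the list alone (camera adjusted p = 3.19e-06, and adjusted p = 0.497 with an estimated correlation). Of 10 small and structural noncoding RNAs, 6 fell, 0 rose and 4 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.00138, and adjusted p = 0.411 with an estimated correlation). The list, called small RNAs for short, as fixed also named the long noncoding RNAs Malat1, Neat1, Snhg1 and Gas5. It named Rn7s1 and Rn7s2 as separate members. Rn7s1, a 7SL RNA of the signal recognition particle that may share reads with its near copy Rn7s2, stood at 238 ± 11.2 CPM in X and 2839 ± 701 CPM in S. Rpph1 and Rmrp, the RNA parts of ribonucleases P and MRP, were 5.95-fold and 3.62-fold lower. The X libraries differed in makeup too: 7SL RNA took 0.0433% and 0.0453% of counts in X, 0.543% and 0.727% in S and 0.624% and 0.604% in C. Mitochondrial ribosomal RNA took 4.61% and 6.92% in X, 2.67% and 2.78% in S and 2.25% and 2.29% in C. Across 7983 abundant genes, which are not independent replicates, log2 differences of X against S ran with transcript GC content at Spearman rho = -0.44, and those of C against S at -0.014. Without X replicate 1 the mitochondrially encoded genes that rose were 2, the oxidative phosphorylation genes that fell were 0 and the small RNAs that fell were 4, and without X replicate 3 they were 1, 2 and 4. Without S replicate 5 they were 1, 3 and 4, and without S replicate 7 they were 2, 4 and 4.

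In total 2873 genes differed between X and S, 1326 higher and 1547 lower in X, so that 46.2% were higher. Scaling by library totals alone gave 3685 genes with 17.1% higher and put the median of all genes at -0.3 on the log2 scale, from -0.021. The GC and length correction, over the 17990 genes with a transcript, gave 1048 higher and 1002 lower, so that 51.1% were higher. The count was 244 without X replicate 1, 583 without X replicate 3, 727 without S replicate 5 and 1049 without S replicate 7, against 4623 by DESeq2 and 712 beyond 1.5-fold.

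The comparison of X with C showed the acute phase at a similar level and other groups apart. Lcn2 and Saa1 had log2 differences of -0.12 ± 0.39 and 0.05 ± 0.45 (SE), and of 28 acute phase genes 3 rose in X, 3 fell and 22 did not pass, with 5 and 6 adjusted over the list alone (camera adjusted p = 0.73). These were 1 and 1 without X replicate 1, 0 and 1 without X replicate 3, 1 and 2 without C replicate 21, 2 and 4 without C replicate 19, and 5 and 6 without S replicate 5 or S replicate 7. Cd14 was 17.1-fold lower in X and Il1rn 4.71-fold lower. Of 27 interferon-stimulated genes, 14 fell, 1 rose and 12 did not pass, and 17 fell adjusted over the list alone. Their median log2 difference was -0.98 (camera adjusted p = 1.3e-05, and adjusted p = 0.511 with an estimated correlation). Rsad2 was 3.73-fold and Ifit1 2.86-fold lower in X. Of 15 immediate early genes, 8 fell, 0 rose and 7 did not pass, and 12 fell adjusted over the list alone (camera adjusted p = 2.98e-05, and adjusted p = 0.511 with an estimated correlation), with Ier3 35.4-fold and Jund, an AP-1 transcription factor, 4.87-fold lower. Of 20 NF-kappaB and Toll-like receptor genes, 11 fell, 1 rose and 8 did not pass, and 14 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.00229, and adjusted p = 0.511 with an estimated correlation). Of 16 neutrophil markers, 7 fell, 0 rose and 9 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.00164, and adjusted p = 0.511 with an estimated correlation), with Ltf 11.7-fold lower. Akap12, a scaffold of protein kinase A, was 20.4-fold lower. By fry, a rotation test, the NF-kappaB list had an adjusted p = 0.0534 and the neutrophil list an adjusted p = 0.0662. In the order interferon, immediate early, NF-kappaB and neutrophil, the counts that fell without X replicate 1 were 5, 2, 3 and 2, those without X replicate 3 were 4, 2, 4 and 5, and those without C replicate 21 were 16, 5, 8 and 3.

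Endothelial and Kupffer markers and part of the hepatocyte genes were higher in X than in C. Of 14 sinusoidal endothelial markers, 8 rose, 2 fell and 4 did not pass, and 11 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.00229, and adjusted p = 0.511 with an estimated correlation). Clec4g stood at 27.9 ± 0.717 CPM in X, 0.889 ± 0.552 CPM in C and 44.8 ± 4.23 CPM in S, and the endothelial growth factor receptor Kdr was 4.44-fold higher in X than in C. Of 12 Kupffer cell markers, 6 rose, 0 fell and 6 did not pass, and 7 rose adjusted over the list alone (camera adjusted p = 0.00181, and adjusted p = 0.511 with an estimated correlation). Vsig4, a complement receptor of these cells, stood at 34.3 ± 1.75 CPM in X, 6.46 ± 0.571 CPM in C and 27.3 ± 1.2 CPM in S. Of 20 bile acid genes, 9 rose, 0 fell and 11 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.00229, and adjusted p = 0.511 with an estimated correlation), with Abcb11 8.53-fold and Cyp8b1 6.58-fold higher. Of 15 pericentral genes, 10 rose, 1 fell and 4 did not pass, and 11 rose adjusted over the list alone (camera adjusted p = 0.00104, and adjusted p = 0.511 with an estimated correlation), with Axin2 4.58-fold higher. Drug metabolism genes passed as a group only in some fits: of 31, 10 rose, 0 fell and 21 did not pass, and 10 rose and 2 fell adjusted over the list alone. The median log2 difference of the list was 0.04 (camera adjusted p = 0.0716, 0.0384 with no filter, 0.000242 without C replicate 21 and 0.0222 without X replicate 1). Without X replicate 3 this list had 4 that rose, and without C replicate 19 it had 10 that rose and 6 that fell. Cyp2e1 was 3.29-fold higher (adjusted p = 0.00833), a call that ended without X replicate 3 (adjusted p = 0.0633). Of 31 complement and coagulation genes, 15 rose, 3 fell and 13 did not pass, and 17 rose adjusted over the list alone (camera adjusted p = 0.001, and adjusted p = 0.511 with an estimated correlation), with Klkb1 10.4-fold higher. Bhmt, which remethylates homocysteine, was 8.52-fold higher. In the order endothelial, Kupffer, bile acid, pericentral and complement, the counts that rose without X replicate 1 were 5, 2, 7, 5 and 5, and those without X replicate 3 were 4, 2, 6, 4 and 5.

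Cholesterol, ribosomal and small or structural RNA genes were lower in X than in C. Of 22 cholesterol genes, 9 fell, 0 rose and 13 did not pass, and 12 fell adjusted over the list alone (camera adjusted p = 0.000355, and adjusted p = 0.511 with an estimated correlation), with Lss, lanosterol synthase, 2.53-fold lower. Of 30 ribosomal protein genes, 15 fell, 0 rose and 15 did not pass, and 16 fell adjusted over the list alone (camera adjusted p = 1.3e-05, and adjusted p = 0.511 with an estimated correlation). Rpl13 was 3.23-fold lower, at 56 ± 0.503 CPM in X against 181 ± 24.6 CPM in C. Of 10 small and structural noncoding RNAs, 7 fell, 0 rose and 3 did not pass, and 7 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.00104, and adjusted p = 0.511 with an estimated correlation), and Rn7s1 was 13.4-fold lower. Of 13 mitochondrially encoded genes, 10 rose, 0 fell and 3 did not pass, and 11 rose adjusted over the list alone (camera adjusted p = 2.98e-05, and adjusted p = 0.511 with an estimated correlation). After the GC and length correction 5 of these rose and 1 fell, and the median went from 0.97 to 0.56. Log2 differences of X against C ran with transcript GC content across the same 7983 genes at Spearman rho = -0.38. In the order cholesterol, ribosomal and small RNA, the counts that fell were 2, 4 and 4 without X replicate 1 and 2, 3 and 4 without X replicate 3, and the mitochondrially encoded genes that rose were 8 and 4. Without C replicate 21 the small RNAs that fell were 4.

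In total 4192 genes differed between X and C, 2033 higher and 2159 lower in X, so that 48.5% were higher. This share was 54.6% with upper quartile scaling and 39.7% with library totals alone, so the balance of the directions depends on the scaling. The count was 704 without X replicate 3, 852 without X replicate 1, 2321 without C replicate 21 and 1099 beyond 1.5-fold.

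**Figure D3:**
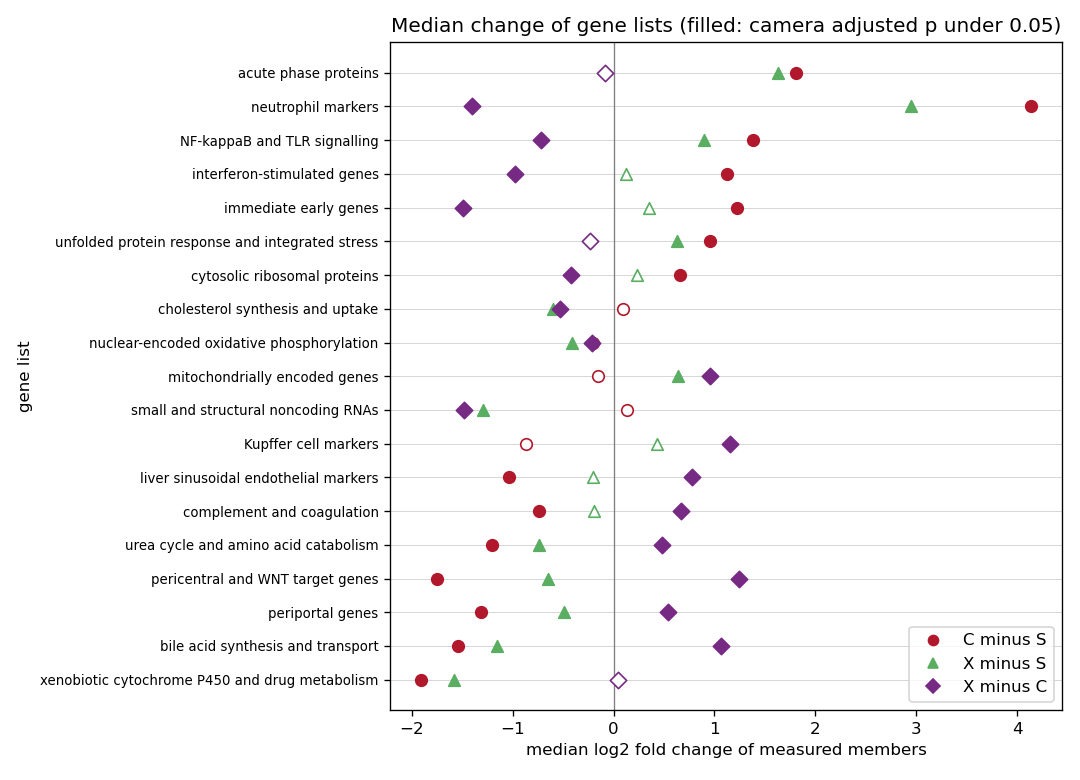
Median log2 fold change of the measured members of 19 gene lists in C minus S, X minus S and X minus C, with a filled symbol where the camera adjusted p was under 0.05 at the preset correlation. Acute phase genes lay at 1.81 and 1.63 against S and at -0.08 in X minus C, whereas interferon-stimulated genes lay at 1.12, 0.12 and -0.98.

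Set on the 6073 genes that separated C from S, X took several positions. X differed from S and not from C for 1347 genes (22.2%), such as Cebpa and Creld2. X differed from C and not from S for 2181 genes (35.9%), such as Rsad2, Vsig4 and Clec4g. It lay between with a call against both for 536 genes (8.83%), such as Cd14, Abcb11 and Klkb1, and passed against neither for 1928 genes (31.7%). Leaving out a library left a single library in its group, so shifts in these shares can follow from lost power alone. Without X replicate 1 these shares were 3.42%, 14.8%, 0.998% and 80.7%, and without X replicate 3 they were 8.62%, 10.6%, 1.71% and 79%. In the same order they were 10.3%, 45.7%, 5.66% and 37.7% without S replicate 5, 14.2%, 40.8%, 8.07% and 36.5% without S replicate 7, 35.7%, 24.1%, 11.3% and 27.6% without C replicate 21, and 22.8%, 42.5%, 11.1% and 20.3% without C replicate 19. Genes higher in both C and X than in S numbered 991, and genes lower in both numbered 937. Independent lists of these sizes would share 187 and 223, but the comparisons share the S libraries, and lists of these sizes from 20 simulated draws with no group effect shared 689 to 764 and 637 to 697. At the threshold itself the simulated draws shared at most 2 and 0. The comparisons that share C had 1250 genes higher in C than in S and lower in X than in C, and 1503 with both directions turned. Independent lists of these sizes would share 305 and 293, and lists of these sizes from the simulated draws shared 800 to 858 and 925 to 1039. At the threshold those draws shared at most 1 and 1. Across the tested genes, log2 differences of C against S and X against S correlated at r = 0.625. Simulated draws of all libraries with no group effect, in which both comparisons again shared S, gave 0.527. The covariance was 1.52 against 0.305 simulated, a difference of 1.21. The S libraries were not split between the comparisons, so part of the excess may come from the shared libraries.

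Galectins were examined because alpha-lactose binds them. Lgals9, which encodes galectin-9, stood at 247 ± 1.29 CPM in C, 195 ± 2.28 CPM in S and 236 ± 11.1 CPM in X. Its adjusted p was 0.0798 for C against S, 0.185 for X against S and 0.769 for X against C, and for C against S it was 0.0088 by DESeq2 and 0.0489 by limma-voom. Lgals3, a galectin of macrophages, had log2 differences of 0.62 ± 0.2 (SE) for C against S (adjusted p = 0.0577) and 0.71 ± 0.2 for X against S (adjusted p = 0.0606). Lgals1 was lower in X, at 1.54 ± 0.275 CPM, than in S, at 5.35 ± 1.52 CPM (adjusted p = 0.0115), a call that ended without X replicate 1 (adjusted p = 0.112), X replicate 3 (adjusted p = 0.0584) or S replicate 5 (adjusted p = 0.0685). Lgals1 was also lower in X than in C (adjusted p = 0.0213), and this ended without X replicate 1 (adjusted p = 0.14), X replicate 3 (adjusted p = 0.0841) or C replicate 21 (adjusted p = 0.0757) and after correction for GC content and length (adjusted p = 0.0538). Havcr2, which encodes the galectin-9 receptor TIM-3, stood at 0.697 ± 0.262 CPM in C, 0.35 ± 0.0418 CPM in S and 0.547 ± 0.182 CPM in X and passed in no comparison. Cd8a, a marker of cytotoxic T cells, lay at or under 0.228 CPM in every group mean and passed in no comparison. Of 8 genes of T cell inhibitory receptors and the galectin-9 axis, 0 passed in X against S, while the list was higher by camera (adjusted p = 0.0384). That call ended with an estimated correlation (adjusted p = 0.411), by fry (adjusted p = 0.0703) and after the GC and length correction (camera adjusted p = 0.0891). In C against S 2 rose and 1 fell (camera adjusted p = 0.581), and in X against C 2 rose and 1 fell. Of 7 galectin genes measured, 3 rose in C against S (1 without S replicate 5, X replicate 1 or X replicate 3), and 5 rose adjusted over the list alone (camera adjusted p = 0.156, and adjusted p = 0.014 by fry). In X against S 1 rose, 1 fell and 5 did not pass, with 2 and 1 adjusted over the list alone (camera adjusted p = 0.186), and none passed without S replicate 5, X replicate 1 or X replicate 3. In X against C 2 fell and 5 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.595), and 0 fell without X replicate 1, without X replicate 3 or after the GC and length correction, and 1 without C replicate 19 or C replicate 21.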

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

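Of the alternatives, 4 were added after the results were seen: counts divided by 4, thinning, the GC and length correction, and leaving out short and mitochondrial genes. Across 558 named gene results and 153 list results no direction was reversed with a call. Requiring a change beyond 1.5-fold left 2753 genes in C minus S, 712 in X minus S and 1099 in X minus C, and DESeq2 gave 4623 in X minus S. After the GC and length correction the genes lower in X than in S were 1002, against 1547. Leaving out 1 library gave 3374 (without S replicate 5) to 5886 (without C replicate 19) genes in C minus S, 244 (without X replicate 1) to 3851 (without C replicate 21) in X minus S, and 704 (without X replicate 3) to 4872 (without C replicate 19) in X minus C. With an estimated correlation 0, 0 and 0 lists passed by camera, against 29, 18 and 16 by fry. Of the named gene results, the test against 1.5-fold weakened 173, the GC and length correction 40, limma-voom 16, totals alone 16 and DESeq2 3, while leaving out X replicate 1 weakened 206, X replicate 3 189, S replicate 5 115 and S replicate 7 93. Simulated groups with no change gave correlations of 0.527, -0.504 and 0.468 for the 3 pairs of comparisons, because each pair shares libraries. The correlation of C minus S with X minus S was 0.747 among genes of at least 8 CPM and ran from 0.5 (without X replicate 3) to 0.697 (without S replicate 7). That of C minus S with X minus C ran from -0.758 (without C replicate 19) to -0.545 (without X replicate 3). That of X minus S with X minus C was 0.144, below its simulated value, 0.304 with no filter and reversed to -0.0845 among genes of at least 8 CPM, and ran from 0.155 (without S replicate 7) to 0.454 (without X replicate 3). Over all tested genes the mean distance was 1.55 between C and S, 1.25 between C and X and 1.18 between S and X, in the same order as over the 500 genes of largest variance. No paired analysis was possible because the groups share no replicate numbers. Each fit without a library left a single library in its group, so a call lost there does not show that the result rested on that library.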

Other observations

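The tests of fewer mitochondria, of the GC and length correction on Rn7s1, on oxidative phosphorylation genes in X against C and on mitochondrially encoded genes were chosen after the results were seen, and Loxl4 was picked after its values were seen. Circadian clock genes split in both C and X against S. Of 19 measured, 5 rose, 8 fell and 6 did not pass in C, and 5 rose, 7 fell and 7 did not pass in X (camera adjusted p = 0.385 and 0.23). Adjusted over the list alone, 5 rose and 9 fell in C, and 5 rose and 8 fell in X. Nr1d1, which encodes the clock repressor REV-ERB alpha, stood at 1.16 ± 0.966 CPM in C, 22.2 ± 5.26 CPM in S and 1.04 ± 0.329 CPM in X, and its call in X against S ended without X replicate 1 (adjusted p = 0.0782). Nr1d2, its paralog, was 3.5-fold lower in C and 3.95-fold lower in X, and Cry1, a repressor of the opposite phase, was 1.99-fold and 2.74-fold higher. Without X replicate 1 the list in X against S had 1 that rose and 1 that fell, without X replicate 3 it had 1 and 3, and without S replicate 5 it had 1 and 4. In C against S the genes that rose were 3 without C replicate 21 and 3 without S replicate 5. The time of day of sampling was not given in the sources used here.

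Of 18 growth hormone and sex-biased liver genes, 9 fell, 1 rose and 8 did not pass in C against S, and 10 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.000829, and adjusted p = 0.344 with an estimated correlation). In X against S 5 fell, 1 rose and 12 did not pass, and 9 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.00952, and adjusted p = 0.411 with an estimated correlation and 0.142 without S replicate 7). In C the genes that fell were 5 without C replicate 21, and in X they were 2 without X replicate 1 and 3 without X replicate 3, while 3 rose without S replicate 7. Ghr, the growth hormone receptor, was 2.91-fold lower and the female-biased repressor Cux2 17.6-fold lower in C than in S. Igfals, a plasma protein gene of another list that encodes a carrier of circulating IGF1, stood at 110.7 ± 2.88 CPM in S, 3.51 ± 1.02 CPM in C and 8.81 ± 0.78 CPM in X. Its 2.51-fold higher level in X than in C ended as a call without X replicate 3 (adjusted p = 0.0599). X was higher than both C and S for 150 genes and lower than both for 437. Loxl4, a lysyl oxidase that crosslinks collagen, stood at 24.7 ± 3.34 CPM in X, 5.71 ± 1.69 CPM in C and 4.91 ± 0.338 CPM in S. Saa4, the constitutive serum amyloid A gene, was 3.24-fold higher in X than in C, a call that ended without X replicate 3 (adjusted p = 0.0597). The counts of genes higher and lower than both were 8 and 22 without X replicate 1, 5 and 51 without X replicate 3, 31 and 122 without S replicate 5, 44 and 126 without S replicate 7, 341 and 590 without C replicate 19, and 105 and 179 after the GC and length correction.

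Short structural RNAs were lower in X, with Rn7s1 at a log2 difference of -3.74 against C. After the GC and length correction Rn7s1 stayed at -3.01, against -3.73 in the same genes uncorrected, so the trend as fitted over all genes did not remove the difference. Few of the other short genes are abundant, as given below. The correction is therefore weakly set at short lengths and cannot decide on a bias there. Library preparation or size selection could not be excluded: the other genes under 300 bases had medians of -0.13 in X minus S and -0.19 in X minus C, a bound written beforehand as speaking against it, but 3 of those 429 genes reach 8 CPM, so that reading was withdrawn after the value was seen. Those 3 genes had medians of 0.86 in X minus S and 1.13 in X minus C, with 2 called higher and 0 lower in each, and are too few to decide. Thinning to equal depth left -3.738, a test that keeps each gene's share by design and so decides nothing about depth, and preparation of the X libraries and treatment cannot be told apart, since the design confounds them.

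Nuclear-encoded oxidative phosphorylation genes were lower in X while mitochondrially encoded genes were higher. The nuclear list was also lower in C than in S, with a median of -0.2 and 4 of 29 genes that fell. Its camera adjusted p there was 0.0297, and 0.698 with an estimated correlation. In X against S the nuclear median stayed at -0.4 after the GC and length correction, from -0.45, which argues against that trend there, while in X against C it shrank to -0.09 from -0.22, so the trend may account for most of that smaller difference. Fewer mitochondria as the whole cause would lower the mitochondrially encoded list too, but its medians were 0.96 in X minus C and 0.64 in X minus S. They stayed above 0 after the correction at 0.56 and 0.39. That rise was part of the pattern already seen, and the X libraries also differed in makeup. These RNA levels therefore cannot decide on the number of mitochondria. The TCA cycle median was 0.03 in X minus C but -0.28 in X minus S, before and after the correction (camera adjusted p = 0.0677, and 0.0244 after it), which goes with fewer mitochondria. That median was -0.37 in C minus S (camera adjusted p = 0.0813, and 0.0468 after the correction), so a lower TCA list was not particular to X. A part of the X against S difference therefore stays open. How much of the mitochondrially encoded rise is due to GC content is also open, and a treatment difference stays untested.

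X lay between C and S for many genes, and a mixture of C and S RNA in the X libraries would give every gene the same share of the difference in CPM, whereas of 576 genes 28.8% had a share under 0.25 and 26.4% a share above 0.75. The median share was 0.218 (interquartile range 0.0891 to 0.413) for 245 genes higher in C and 0.7 (0.525 to 0.849) for 331 lower in C. After the GC and length correction 2668 genes had opposite calls in C minus S and X minus C, against 2630 uncorrected. These comparisons share the C libraries, so neither count alone places X between C and S. A place midway on the log2 scale gives low shares of CPM to genes higher in C and high shares to genes lower in C, so the split of shares does not show which set lay nearer to S. A batch of the X libraries and a treatment difference both stay open.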
